A study of Mus musculus with 12 samples.

How the data were processed

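The table used held 142647 Ensembl transcripts of 55471 genes for 12 libraries, with 3 values per transcript and library. Estimated counts were deposited by the authors as rounded read counts per transcript, and the tool that made them is not named. RPKM values were deposited by the authors as values scaled by transcript length and library size, per the file headers. TPM values were deposited by the authors beside them and were not used here. Per the submitters' processing notes, reads were aligned with TopHat2 2.0.12 and transcripts quantified with Cufflinks 2.1.1 and Cuffdiff, of which no version is given. RNA was prepared with RNeasy Mini columns and TruSeq kits from 1 ug of total RNA, per the submitters' notes.

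Those notes name the cattle build UMD3.1, whereas the coordinates of the table match mouse GRCm38. Of 141429 transcript IDs shared with GENCODE M21, 141073 (99.75%) had identical coordinates, so positions are given on GRCm38. The label C was read as control, and IP is not expanded by the labels. The labels do not say whether the libraries of a group are separate animals, so p-values measure the spread between these samples. Before the data were examined the groups, the comparisons, the gene lists, the rule for naming genes and the alternatives were fixed.

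Transcript counts were summed per gene. The plan foresaw limma on FPKM, or edgeR if the table held counts; the table holds counts, so edgeR 4.0.16 in R 4.3.3 was used. Genes passed filterByExpr (minimum count 10, minimum total 15), which left 16908 genes, and libraries were scaled by TMM with factors from 0.681 to 1.13. One model with 6 group means was fitted to the 12 libraries (residual degrees of freedom 6, common dispersion 0.0472). Each comparison used edgeR's robust quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p of at most 0.05. Comparisons were oral and IP against control and IP against oral in each tissue, spleen against MLN over the groups, and the differences between tissues of the oral and IP changes (interaction tests).

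The rule named up to 10 called genes per direction by size of change, or 5 for IP against oral and for the tissue differences. The group mean had to reach 1 RPKM in the higher group, and both libraries of a group had to lie beyond both of the other group. Clone-named and predicted genes and variable segments of immunoglobulins and T cell receptors were not named. Where fewer than 5 passed, the 5 smallest unadjusted p-values were named, without a claim of change. Up to 4 members of each list that passed were named too, and 12 genes fixed beforehand: Ifng, Nos2, Cxcl9, Gbp2, Il17a, Il10, Tnf, Il1b, S100a8, Jchain, Slc40a1 and Alas2. For a gene with 0 counts in a group a fold was given as a bound, with a floor of 3 counts over the group (0.0820 to 0.125 CPM by group). Floors cover counting error only and not the spread between animals.

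Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation, with Benjamini-Hochberg adjustment over the 31 lists of a comparison and at least 3 members tested. The 31 lists were written by hand from general knowledge: interferon-gamma-induced, type I interferon-induced, Th1 and cytotoxic lymphocyte, Th17, Th2, regulatory T cell, T cell markers, NK cell markers, B cell markers, germinal centre B cell, plasma cell, immunoglobulin constant, red pulp macrophage, monocyte, neutrophil, dendritic cell, inflammatory cytokines and chemokines, granuloma and activated macrophage, MHC class II, complement, erythroid, megakaryocyte and platelet, proliferation, cholesterol synthesis, immediate early and heat shock, pancreatic acinar, adipose tissue, intestinal epithelial, stromal and endothelial, mesothelial, and skeletal muscle. The stromal list counts Ccl21a with 2 entries, 1 of them on the unplaced sequence JH584294.1.

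Alternatives fixed beforehand were DESeq2 1.42.0 in place of edgeR, no filter (26011 genes), a strict filter of 100 counts in 2 libraries (12347 genes), relative log expression scaling, a fit to the 6 libraries of a tissue, no trend and no robust spread, limma on log2(RPKM + 1), a replicate block, and each library left out in turn. Scaling on the T and B cell marker lists alone, called marker scaling here, was added after the pancreatic and adipose shares had been seen. The correlation of oral and IP changes was compared with 20 simulations that share the control libraries.

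The edgeR code was tested on simulated data of 16908 genes with 200 changed, 100 at 2-fold and 100 at 4-fold. In MLN oral 27% of the 2-fold and 66% of the 4-fold changes were found, in MLN IP 39% and 66%, in spleen oral 27% and 67% and in spleen IP 34% and 76%. False calls numbered 10, 9, 8 and 6, and 0 had the wrong direction. In each comparison the false calls were a larger share of the calls than the threshold for a call aims at. The share was largest in MLN oral, with 10 beside 27 and 66 true ones, and only slightly above the aim in spleen IP, with 6 beside 34 and 76. Replicate libraries had Spearman correlations of 0.969 to 0.990, with the largest spread beyond counting error in MLN oral. Chi-square per degree of freedom between replicates was 263 in MLN oral and 17.6 in spleen oral. The simulation found nearly the same shares in both, so its shares cannot be taken as the power in the real MLN oral libraries. Raw reads and single transcripts were not analysed here. Results of some genes are not reported here.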

Results

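RNA-seq of mouse mesenteric lymph node (MLN) and spleen was compared 6 weeks after infection with Mycobacterium avium subsp. paratuberculosis in C57BL/6 mice. The 12 libraries formed 6 groups of 2: MLN control (1, 3), MLN oral (4, 5), MLN IP (3, 4), spleen control (2, 3), spleen oral (1, 4) and spleen IP (2, 5). Estimated counts per library, in the same order, were 14916790, 15461266, 11515548, 16091056, 15293895, 17415587, 14998237, 17428347, 15623411, 18149787, 16785415 and 15468925. Between 14505 and 15871 genes had at least 10 counts in a library, and 16908 genes were tested. All fold changes are log2 values from edgeR's quasi-likelihood test with n = 2 libraries per group, and adjusted p-values are by Benjamini-Hochberg.

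Pancreatic digestive enzymes and fat cell genes took up large and unequal parts of the MLN libraries. The pancreatic acinar list held 3.33% and 4.07% of all counts in MLN control 1 and 3, 24.4% and 4.05% in MLN oral 4 and 5, and 0.316% and 0.0025% in MLN IP 3 and 4. Adipose genes held 4.30% and 2.49% in the MLN controls, 1.28% and 2.11% in MLN oral, and 0.717% and 0.454% in MLN IP. With the copies of amylase 2 added, the pancreatic shares were 5.13%, 6.86%, 33.5%, 6.89%, 0.492% and 0.0026%. Mitochondrial genes held 8.52% and 8.34% in MLN control, 7.89% and 6.64% in MLN oral and 3.67% and 3.99% in MLN IP. Spleen libraries held 0.0419% to 0.0691% on adipose genes and 3.11% to 8.32% on haemoglobin genes. Counts on Y-linked genes were 0 in every library, and Xist, transcribed from the inactive X chromosome, stood at 660 to 1090 CPM (counts scaled to library size). The first principal component held 67.9% of the variance and the second 9.96%.

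**Figure D1:**
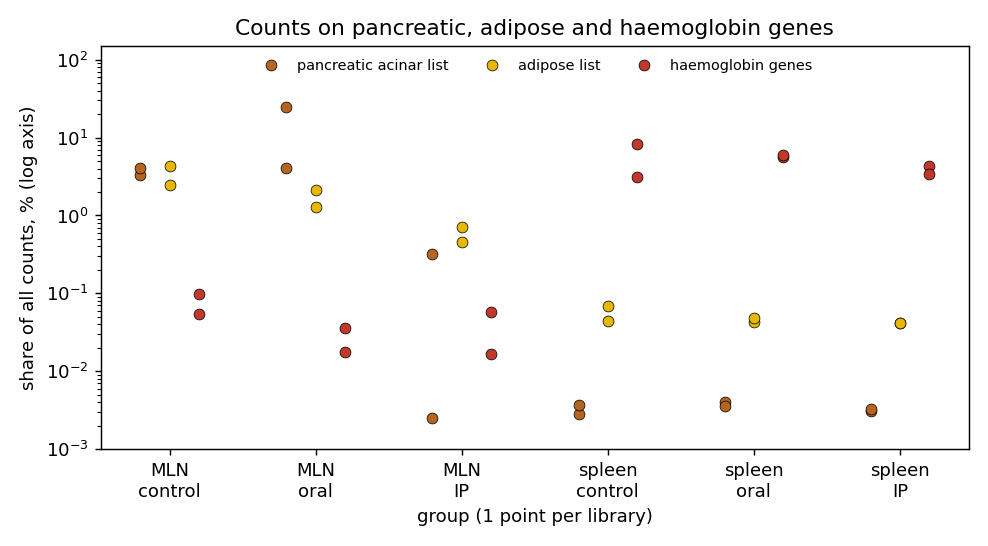
Share of all counts in % (log axis) on the pancreatic acinar list, the adipose list and the haemoglobin genes, by group; each point is 1 library. MLN oral 4 stands highest for pancreas, and the MLN IP libraries stand lowest of the MLN for fat.

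Genes of red cell formation were far higher in spleen, and fat genes, with pancreatic genes in most MLN libraries, in MLN. Rhag (ENSMUSG00000023926, chr17:40811126-40840754, GRCm38), a red cell membrane protein, stood at 161, 162 and 123 CPM in spleen control, oral and IP and at 0, 0 and 0.0889 CPM in the MLN groups, and was called (adjusted p = 1.28e-04). Slc4a1, the band 3 anion exchanger, had a log2 difference spleen minus MLN of 11.76 (SE 0.756, adjusted p = 7.44e-06). The haem synthesis enzyme Alas2 was 7.73 higher (SE 0.478, adjusted p = 4.39e-06) and the iron exporter Slc40a1 3.596 higher (SE 0.165, adjusted p = 7.80e-08). Amy2a5 (ENSMUSG00000074268, chr3:113247178-113258837), a pancreatic amylase of a family whose copies share reads, stood at 12706, 105900 and 100.89 CPM in MLN control, oral and IP (7.408 in MLN IP 4) and at 1.05, 0.109 and 0.0871 CPM in spleen control, oral and IP (adjusted p = 5.36e-04). Il17a, the Th17 cytokine, had 0 counts in the spleen libraries.

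Across all 16908 genes, 4707 were higher and 4514 lower in spleen, and 10134 had an unadjusted p under 0.05. Of the 31 lists, 15 passed as sets by limma's camera with the preset correlation. Called higher were 21 of 22 erythroid genes (21 adjusted over the list alone, median 8.22, adjusted p = 9.62e-28, and adjusted p = 0.234 with an estimated correlation), 11 of 12 megakaryocyte and platelet genes (11 alone, 6.18, adjusted p = 1.23e-22, and 0.127 with it) and 14 of 14 red pulp macrophage markers (14 alone, 1.38, adjusted p = 2.31e-13, and 0.303). Neutrophil genes were higher in 16 of 17 (16 alone, 2.53, adjusted p = 2.67e-06, and 0.520 with an estimated correlation), proliferation genes in 18 of 18 (18 alone, 1.88, adjusted p = 5.84e-08, and 0.524) and B cell markers in 10 of 14 (11 alone, 0.58, adjusted p = 0.00152, and 0.575). T cell markers were lower in 16 of 16 (16 alone, -0.72, adjusted p = 5.31e-06, and 0.471 with an estimated correlation), adipose genes in 14 of 14 (14 alone, -8.12, adjusted p = 1.77e-34, and 0.127) and pancreatic acinar genes in 19 of 19 (19 alone, adjusted p = 2.38e-06, and 0.575). Of the 84 genes named by rule for this comparison and called, 81 kept the call in each of the 12 fits that left out 1 library; the total ranged from 8158 to 9198.

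Interferon-gamma target genes rose in the MLN of the IP group. Tap1 (ENSMUSG00000037321, chr17:34187553-34197225), which loads peptides for MHC class I, went from 161 CPM (SD 6.59) in control to 425 CPM (SD 1.01), a change of 1.40 (SE 0.152, adjusted p = 8.10e-04). Ifng (ENSMUSG00000055170, chr10:118441046-118445892) rose by 3.13 (SE 0.569, adjusted p = 0.00437), from 0.581 to 5.18 CPM. Acod1 (ENSMUSG00000022126, chr14:103046977-103056573), the itaconate-forming enzyme of activated macrophages, rose by 5.23 (SE 0.82, adjusted p = 0.0031), and the nitric oxide synthase Nos2 by 3.90 (SE 0.956, adjusted p = 0.0206), from 1.81 to 27.1 CPM (SD 29.9). Lactoferrin (Ltf) rose by 4.02 (SE 0.711, adjusted p = 0.00641). Igha (ENSMUSG00000095079, chr12:113254830-113260236), the IgA heavy chain, rose by 2.84 (SE 0.31, adjusted p = 8.10e-04), from 992 CPM (SD 31.6) to 7111 CPM (SD 901). Genes of fat and of the mesothelium fell: Scd1 (ENSMUSG00000037071, chr19:44394455-44407879), a fatty acid desaturase, by 2.91 (SE 0.347, adjusted p = 0.0011) and Upk3b (ENSMUSG00000042985, chr5:136038496-136046487), a mesothelial membrane protein, by 4.98 (SE 0.809, adjusted p = 0.00503).

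In total 1919 genes were higher and 2201 lower in MLN IP than in MLN control, and 6493 had an unadjusted p under 0.05. Scaled on T and B cell markers alone, the split was 265 higher and 3596 lower, the median of all genes moving from 0.004 to -0.399. In MLN IP that scaling is thus a check for genes that rose, and a weak one for genes that fell. Without MLN control 1 the counts were 888 and 1180, without MLN control 3 598 and 1234, without MLN IP 3 916 and 1185, and without MLN IP 4 846 and 699. Nos2 lost its call without MLN control 1, MLN control 3 or MLN IP 3. Acod1, Tap1, Ifng, Ltf, Igha, Scd1 and Upk3b kept theirs in all 12 of these fits and under marker scaling.

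Of 31 interferon-gamma-induced genes, 28 were higher in MLN IP (30 adjusted over the list alone, median 1.39, camera adjusted p = 5.71e-19, and adjusted p = 0.301 with an estimated correlation). The GTPase Igtp rose by 2.15 (SE 0.259), the transcription factor Irf1 by 1.20 (SE 0.175) and the chemokine Cxcl9 by 2.18 (SE 0.525, adjusted p = 0.0193). Gbp5 and Gbp2, 2.48 (SE 0.336) and 1.97 (SE 0.399) higher, belong to a family of near-identical copies, so the split between copies is uncertain. Marker scaling left 16 of the 31 called, and 17, 26, 13 and 15 were called without MLN IP 3, MLN IP 4, MLN control 1 and MLN control 3. Gbp2 lost its call without MLN control 1 or 3, and Cxcl9 also without MLN IP 3. The type I interferon-induced list had 8 of 24 higher and 1 lower (8 and 1 alone, median 0.59, adjusted p = 5.13e-04, and adjusted p = 0.526 with an estimated correlation), with Oas3 at 2.01 (SE 0.362) and Ifi27l2a at -1.61 (SE 0.278).

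Several T cell genes of the Th1 and regulatory kind rose in MLN IP. Tbx21 (T-bet), which drives Th1 cells, rose by 1.84 (SE 0.262, adjusted p = 0.00187), the Il12 receptor Il12rb1 by 2.02 (SE 0.255) and Cxcr3 by 1.31 (SE 0.187). In the Th1 and cytotoxic lymphocyte list 13 of 20 were higher (15 alone, median 0.94, camera adjusted p = 8.38e-09, and adjusted p = 0.301 with an estimated correlation). Regulatory T cell genes were higher in 7 of 12 (9 alone, 0.86, adjusted p = 9.77e-05, and 0.301 with it), among them the checkpoint receptor Lag3 at 1.52 (SE 0.258). T cell markers were higher in 7 of 16 (9 alone, 0.52, adjusted p = 1.44e-04, and 0.526), with Cd4 at 1.16 (SE 0.176) and Cd6 at 1.24 (SE 0.186). Marker scaling left 8 Th1 calls, while the T cell markers define that scaling and cannot be judged by it. Without MLN IP 3, MLN IP 4, MLN control 1 and MLN control 3 the Th1 calls were 8, 9, 6 and 9 and the T cell calls 4 each.

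Several antibody genes rose in MLN IP. Besides Igha, the kappa chain constant region Igkc rose by 2.04 (SE 0.395, adjusted p = 0.00642) and Ighg1, IgG1, by 3.37 (SE 0.71, adjusted p = 0.0128); reads of these segments are shared between related copies. Immunoglobulin constant genes were higher in 3 of 12 (5 alone, median 0.58, camera adjusted p = 0.00344, and adjusted p = 0.417 with an estimated correlation) and plasma cell genes in 6 of 14 (10 alone, 0.60, adjusted p = 0.00198, and 0.526 with it). Of 187 immunoglobulin variable segments tested, 56 were higher and 1 lower. Germinal centre genes were higher in 4 of 11 (4 alone, 0.38, adjusted p = 0.0438, and 0.526), and 4 of 14 B cell markers were called although that list did not pass (4 alone, 0.33, adjusted p = 0.070). Germinal centre levels overlapped, at 5.133 and 4.63 in MLN IP 3 and 4 against 4.337 and 4.854 in the controls. Plasma cell calls fell to 0, 5, 0 and 3 without MLN IP 3, MLN IP 4, MLN control 1 and MLN control 3, and to 1 under marker scaling. Igkc lost its call without MLN control 1, and Ighg1 without MLN control 1, MLN control 3 or MLN IP 3.

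Several neutrophil and macrophage genes were higher as well. The neutrophil list had 10 of 17 higher (15 alone, median 2.47, camera adjusted p = 1.78e-07, and adjusted p = 0.395 with an estimated correlation), with Csf3r, the receptor for the neutrophil growth factor, at 2.14 (SE 0.356) and Lcn2 at 2.69 (SE 0.445). Inflammatory cytokines and chemokines had 8 of 22 higher (17 alone, 1.17, adjusted p = 9.18e-06, and 0.301 with it), led in p by Il1b at 2.52 (SE 0.426, adjusted p = 0.00426). Granuloma and activated macrophage genes had 9 of 19 higher and 1 lower (9 and 1 alone, 1.08, adjusted p = 0.00461, and 0.526), with Cd68 at 1.45 (SE 0.222). Red pulp macrophage markers had 9 of 14 higher and 1 lower (9 and 2 alone, 0.82, adjusted p = 9.46e-04, and 0.526), and complement genes 6 of 14 higher (7 higher and 1 lower alone, 0.71, adjusted p = 0.00713, and 0.536). Monocyte markers had 3 of 14 higher and 1 lower (5 and 1 alone, 0.24, but -0.13 under marker scaling, adjusted p = 0.0216, and 0.526), with Ly6c2 at 1.94 (SE 0.28) and F13a1 at -1.95 (SE 0.592). MHC class II genes had 7 of 10 higher (8 alone, 0.82, adjusted p = 2.57e-04, and 0.395), among them Cd74 at 1.18 (SE 0.187).

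Each of these counts moved when 1 library was left out. In the order MLN IP 3, MLN IP 4, MLN control 1 and MLN control 3, the neutrophil calls were 5, 7, 3 and 5, the inflammatory calls 3, 7, 4 and 5, the complement calls 1, 2, 1 and 1 and the MHC class II calls 5, 5, 4 and 5. Granuloma genes had 3, 9, 2 and 2 called higher in that order. The median level of that list was 5.09 in MLN IP 3 but 3.12 in MLN IP 4, below the 3.33 and 3.43 of the controls, although the median change without MLN IP 3 was 0.677. The monocyte level was likewise 5.68 in MLN IP 4 against 5.80 and 5.76 in the controls. F13a1 lost its call in 7 of the 12 fits, among them those without MLN control 1, MLN control 3, MLN IP 4, spleen control 2, spleen control 3, spleen IP 2 and spleen IP 5. The neutrophil list also had 7 called without any 1 of the spleen control or spleen IP libraries. Under marker scaling 5 neutrophil, 2 inflammatory, 4 granuloma, 1 complement and 2 MHC class II genes were called higher.

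Genes of fat and mesothelium, and some of sterol synthesis, were lower. All 14 adipose genes tested were lower in MLN IP (14 alone, median -2.69, camera adjusted p = 5.06e-12, and adjusted p = 0.301 with an estimated correlation), the adipocyte gene Adig by 3.67 (SE 0.377, adjusted p = 8.10e-04) and leptin (Lep) by 3.16 (SE 0.475). All 8 mesothelial genes were lower (8 alone, -4.28, adjusted p = 1.12e-07, and 0.301 with it), the transcription factor Wt1 by 3.92 (SE 0.497, adjusted p = 0.00136). Cholesterol synthesis genes were lower in 5 of 15 (1 higher and 5 lower alone, -0.30, adjusted p = 0.0161, and 0.526), with Insig1 at -2.12 (SE 0.257), though the list level in MLN IP 4 (5.074) lay between those of the controls (5.374 and 5.025). Pancreatic acinar genes passed as a set with a median of -4.33 (adjusted p = 1.31e-04, and 0.526) but edgeR called 0 of 19 (0 alone); DESeq2 called 4 lower, limma on RPKM 5, and edgeR 19 lower without MLN IP 3. Proliferation genes were higher in 4 of 18 (4 alone, 1.07, adjusted p = 1.44e-04, and 0.526), in 14 without spleen control 2 or 3, and in 0 without MLN IP 3, MLN IP 4, MLN control 1 or MLN control 3. Adipose calls were 13, 8, 9 and 13 and mesothelial calls 4, 2, 7 and 5 in that order of libraries, and marker scaling left 14 and 8.

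Lists that did not pass in MLN IP were Th17 (1 of 8 higher, 1 lower, as many alone, median -0.21), Th2 (1 of 6 higher, 1 lower, 3 and 1 alone, 0.53), NK cell markers (1 of 12 higher, 4 lower, 1 and 6 alone, -0.92, adjusted p = 0.109) and dendritic cell markers (5 of 14 higher, 2 lower, 5 and 2 alone, 0.56, adjusted p = 0.0635). Marker scaling called 0 NK genes higher and 8 lower. Erythroid genes (0 called, 0 alone, median -0.33, or -0.20 with genes at their bound), megakaryocyte genes (2 of 12 higher, 1 lower, 2 and 1 alone, -0.27, or 0 at the bound, although the mean was 0.08) and immediate early and heat shock genes (3 of 15 higher, 1 alone, 0.14) did not pass either. Intestinal epithelial (1 of 10 higher, 2 lower, 2 and 2 alone, -0.40, or -0.32 at the bound), stromal and endothelial (3 of 19 higher, 1 lower, 3 and 1 alone, 0.05) and skeletal muscle genes (1 of 6 lower, 0 alone, -0.71, or 0.07 at the bound) also stayed above the threshold. Tnf was higher by 0.83 (SE 0.195, adjusted p = 0.0128) and Jchain, the chain that joins IgA and IgM, by 1.20 (SE 0.37, adjusted p = 0.0404), whereas S100a8 at 2.09 (SE 0.702, adjusted p = 0.0637), Il10, Slc40a1, Alas2 and Il17a were not called. Tnf lost its call without MLN control 3, MLN IP 3 or MLN IP 4 and under marker scaling. Jchain lost it under marker scaling and without MLN control 1, MLN oral 4, MLN oral 5, MLN IP 3, spleen IP 2 or spleen IP 5.

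Several genes with the largest changes in MLN IP were near 0 in a group. Mcpt8, a basophil protease, had 0 counts in MLN control and 0.901 CPM in MLN IP, at least 8.78-fold higher (floor of 3 counts over the group). Cldn22, a tight junction protein, had 0 counts in MLN IP and was at least 68-fold lower, and the Rnu3b1 to Rnu3b4 small nucleolar RNA copies, which carry identical values, at least 13.8-fold lower. Ms4a3 stood at 0.0684 CPM in control and 1.98 in IP, and Reg3a at 5.98 and 0.0592. Mcpt8, Ms4a3 and Cldn22 lost their calls without MLN control 1 or 3, Reg3a without MLN control 1, MLN IP 3 or MLN IP 4, and the Rnu3b copies without any of those 4 libraries.

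**Figure D2:**
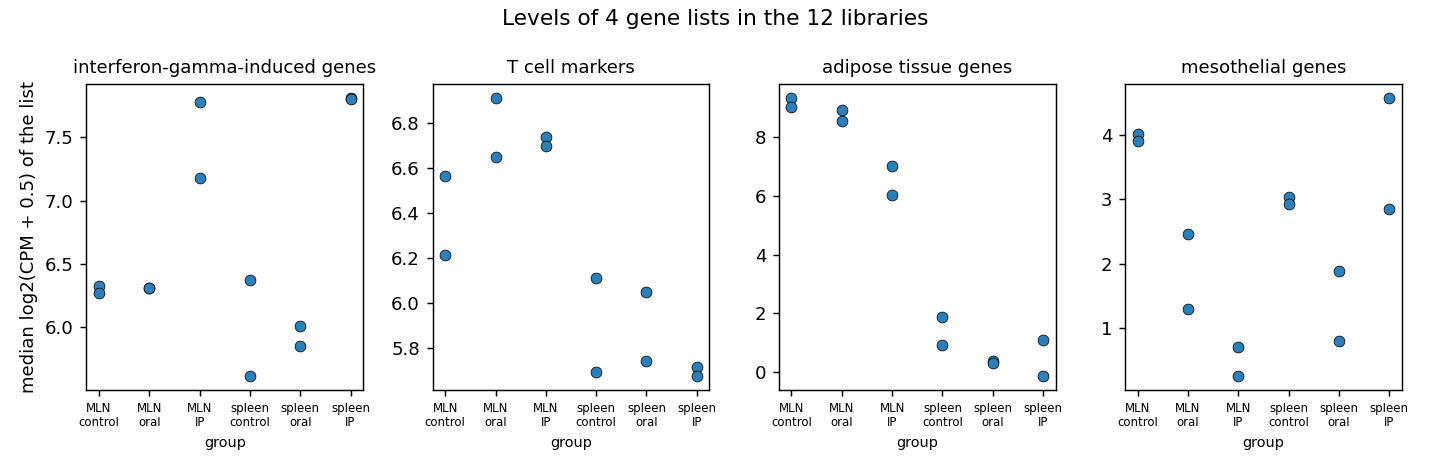
Median log2(CPM + 0.5) of the interferon-gamma, T cell, adipose and mesothelial lists in the 12 libraries, by group; each point is 1 library. The interferon-gamma list is highest in the IP groups of both tissues, and fat and mesothelium are lowest in MLN IP among the MLN groups.

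Dbp, a transcription factor under control of the circadian clock, was the 1 gene called in MLN oral against control. Dbp (ENSMUSG00000059824, chr7:45705088-45710203) rose from 23.4 CPM (SD 1.19) to 61.9 CPM (SD 8.87), a change of 1.40 (SE 0.155, adjusted p = 0.0318). The clock gene Per3 stood at 8.90 and 24.5 CPM (1.47, SE 0.216, adjusted p = 0.124) and was not called. The lipoxygenase Alox15 stood at 16.7 (SD 4.43) and 2.0 CPM (-3.05, SE 0.435, adjusted p = 0.124), not called. Ccl19-ps1, whose reads may be shared with a near-identical copy, had 0 counts in MLN oral, at least 13.2-fold lower and not called (adjusted p = 0.124). Ifng at -0.52 (SE 0.717, adjusted p = 0.839), Cxcl9 at -0.48 (SE 0.51, adjusted p = 0.774), Gbp2 at 0.01 (SE 0.388, adjusted p = 0.999) and Tnf at -0.12 (SE 0.2, adjusted p = 0.878) were not called.

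By edgeR's quasi-likelihood test 1 gene was higher and 0 lower in MLN oral, with 1787 at an unadjusted p under 0.05; marker scaling gave 0 higher and 1 lower with a median of all genes of -0.411. DESeq2 called 68 higher and 70 lower. Dropping MLN oral 5 gave 177 higher and 70 lower, dropping MLN control 3 gave 0 higher and 1 lower, and dropping MLN IP 3, MLN IP 4, spleen oral 1, spleen oral 4, spleen IP 2 or spleen IP 5 gave 0. Dbp lost its call in those 6 fits, without MLN control 1 or 3, in the fit to the MLN libraries alone, without trend and robust spread, with limma on RPKM and under marker scaling.

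As sets, T cell, B cell and antigen presentation genes were higher in MLN oral, with 0 members called over all genes in each. T cell markers had a median of 0.42 (2 of 16 higher adjusted over the list alone, camera adjusted p = 1.75e-07, and adjusted p = 0.646 with an estimated correlation), B cell markers 0.45 (1 of 14 alone, adjusted p = 7.17e-06, and 0.699 with it) and MHC class II genes 0.36 (1 of 10 alone, adjusted p = 9.17e-04, and 0.695). Regulatory T cell genes stood at 0.40 (2 of 12 alone, adjusted p = 0.0020, and 0.646 with an estimated correlation), immediate early and heat shock genes at 0.44 (1 of 15 alone, adjusted p = 0.00608, and 0.757) and intestinal epithelial genes at 0.49 (1 of 10 alone, adjusted p = 0.0281, and 0.558). Proliferation genes (0.45, 0 alone, adjusted p = 0.0136) and pancreatic acinar genes (1.89, 0 alone, adjusted p = 0.0248) also passed, each at adjusted p = 0.937 with an estimated correlation. Lower as sets were mesothelial genes at -2.10 (6 of 8 alone, adjusted p = 9.46e-10, and 0.558 with an estimated correlation), adipose genes at -0.78 (1 of 14 alone, adjusted p = 2.68e-04, and 0.757) and cholesterol synthesis genes at -0.18 (adjusted p = 0.00626, and 0.757). Interferon-gamma-induced genes had a median of 0.09 and did not pass (adjusted p = 0.679). Marker scaling shifts the median of all genes to -0.411. The medians of the MHC class II, regulatory T cell, immediate early and heat shock, proliferation and intestinal epithelial lists are of about that size, so these rises depend on the scaling. The T and B cell markers define that scaling and cannot be judged by it. The median level of the immediate early and heat shock list was 4.61 in MLN oral 4 and 5.38 in MLN oral 5 against 4.63 and 4.74 in the controls. That of the MHC class II list was 8.894 and 8.921 against 8.491 and 8.912, and that of the pancreatic list 12.88 and 10.34 against 10.20 and 10.36, so the libraries of the groups overlapped in all 3 lists.

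MLN IP was higher than MLN oral for interferon-gamma targets, too. Acod1 was 5.76 higher (SE 0.888, adjusted p = 0.0146), Ifng 3.65 (SE 0.618, adjusted p = 0.0154), Tap1 1.05 (SE 0.151, adjusted p = 0.0139) and Il1b 2.65 (SE 0.439, adjusted p = 0.0168). Igha was 2.61 higher (SE 0.308, adjusted p = 0.00733) and the fractalkine receptor Cx3cr1 1.53 higher (SE 0.191, adjusted p = 0.00838). Adig was 2.39 lower (SE 0.364, adjusted p = 0.0146) and the antimicrobial lectin Reg3b 4.61 lower (SE 0.765, adjusted p = 0.0205). Nos2 at 3.44 (SE 0.944, adjusted p = 0.0644) and S100a8 at 2.84 (SE 0.738, adjusted p = 0.0592) were not called. Ccl19-ps1, with 0 counts in MLN oral and 88 in each MLN IP library, was at least 38.8-fold higher, with the same uncertainty over its copy, and the methionine enzyme Mat1a, with 0 counts in MLN IP, at least 73.2-fold lower.

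The comparison of MLN IP with MLN oral gave 469 higher and 611 lower, with 4381 at an unadjusted p under 0.05. The total was 30 without MLN oral 4, 2235 without MLN oral 5, 138 without MLN IP 3, 273 without MLN IP 4, 585 without spleen oral 1 and 594 without spleen oral 4. Of 58 named genes called, Ccl19-ps1 was called in all 12 fits, and Acod1, Tap1, Igha, Cx3cr1, Il1b, Adig and Reg3b in all but the fit without MLN oral 4, the library rich in pancreas. Ifng also lost its call without MLN IP 3, and Mat1a without MLN IP 3 or MLN IP 4. Interferon-gamma-induced genes were higher in 22 of 31 (29 alone, median 1.23, camera adjusted p = 2.51e-29, and adjusted p = 0.202 with an estimated correlation), but in 0 without MLN oral 4, 5 without MLN IP 3 and 14 under marker scaling. Th1 genes were higher in 9 of 20 (12 alone, 0.80, adjusted p = 8.87e-11, and 0.202 with it), inflammatory genes in 6 of 22 (15 alone, 1.28, adjusted p = 2.89e-08, and 0.202) and neutrophil genes in 4 of 17 (16 alone, 2.43, adjusted p = 4.69e-13, and 0.231). Adipose genes were lower in 6 of 14 (13 alone, -1.82, adjusted p = 5.79e-12, and 0.231). Without MLN oral 4 all genes together gave 8 higher and 22 lower, without MLN IP 3 33 and 105, and under marker scaling 108 and 189, so these list counts rest on those libraries and on the scaling. T cell markers (0.04, adjusted p = 0.217) and B cell markers (-0.09, adjusted p = 0.491) did not pass.

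In spleen, the IP group had a sharp rise of genes that interferon-gamma induces. Gbp2b (ENSMUSG00000040264, chr3:142594847-142619179), a guanylate-binding protein, went from 2.68 CPM (SD 1.83) in control to 145 CPM (SD 27.2), a change of 5.76 (SE 0.427, adjusted p = 0.00159). Apol11a (ENSMUSG00000091650, chr15:77508271-77518051), an apolipoprotein L, rose by 4.82 (SE 0.502, adjusted p = 0.0052), from 3.97 to 112 CPM, and the ubiquitin-like Ubd by 3.23 (SE 0.29, adjusted p = 0.00159). Serpina3f, a protease inhibitor, rose by 3.57 (SE 0.304, adjusted p = 0.00159) and the cytokine Il27 by 2.87 (SE 0.454, adjusted p = 0.0191). Gbp2b, Apol11a and Serpina3f share reads with near-identical copies, so the split within each family is uncertain. The lectin Cd209b (ENSMUSG00000065987, chr8:3917655-3926844), made by marginal zone macrophages, fell by 2.96 (SE 0.341, adjusted p = 0.0052), from 27.7 CPM (SD 7.24) to 3.56 CPM (SD 1.55). Siglech, a plasmacytoid dendritic cell receptor, fell by 1.74 (SE 0.267, adjusted p = 0.0157) and the growth factor carrier Igfbp3 by 1.05 (SE 0.18, adjusted p = 0.0275), the latter not called under marker scaling.

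In the spleen, 117 genes were higher and 4 lower in IP than in control, and 1906 had an unadjusted p under 0.05. The total was 12 without spleen control 3, 25 without spleen IP 2, 51 without spleen IP 5, 61 without MLN control 1, 60 without MLN control 3, 72 without spleen oral 1 and 72 without spleen oral 4. Gbp2b, Apol11a, Serpina3f, Ubd, Cd209b and Tgtp1 kept the call in all 12 fits, while Siglech lost it without spleen control 2, spleen IP 2 or spleen IP 5. Il27 lost it without any 1 of the spleen control or spleen IP libraries, and Igfbp3 also without MLN control 1 or 3. Tnf rose by 1.46 (SE 0.199, adjusted p = 0.00843) and Gbp2 by 2.20 (SE 0.401, adjusted p = 0.0496). Tnf lost its call without spleen control 2, spleen control 3 or spleen IP 2, and Gbp2 was called without MLN IP 3, MLN IP 4 or spleen control 2 but lost without any 1 of the other 9. Ifng at 2.23 (SE 0.512, adjusted p = 0.082), Cxcl9 at 1.98 (SE 0.521, adjusted p = 0.170) and Il1b at 1.21 (SE 0.378, adjusted p = 0.227) were not called. Ccl19-ps1 had 0 counts in spleen IP, at least 17.4-fold lower (adjusted p = 0.0113) with the copy uncertainty given above, and lost its call without spleen control 3 or spleen IP 2.

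Of the 31 interferon-gamma-induced genes, 23 were higher in spleen IP (30 alone, median 1.70, camera adjusted p = 2.75e-91, and adjusted p = 0.0504 with an estimated correlation). Psmb9, a subunit of the immunoproteasome, rose by 1.30 (SE 0.147, adjusted p = 0.00493) and Tap1 by 1.32 (SE 0.152, adjusted p = 0.00515). The list count was 2 without spleen control 3, 8 without spleen IP 2, 11 without spleen IP 5, 14 without MLN control 1 and 13 without MLN control 3; Psmb9 and Tap1 lost their calls without spleen control 3. Inflammatory genes had 2 of 22 higher (13 higher and 1 lower alone, 1.34, adjusted p = 5.46e-11, and 0.233 with an estimated correlation), or 0 without spleen control 2, spleen control 3 or spleen IP 2 and 1 without spleen IP 5. Granuloma genes had 1 of 19 higher (6 alone, 1.17, adjusted p = 2.08e-05, and 0.502) and MHC class II genes 2 of 10 (5 alone, 0.49, adjusted p = 8.25e-06, and 0.498). With 0 called over all genes, higher as sets were red pulp markers (8 of 14 alone, 0.69, adjusted p = 4.09e-09, and 0.498), neutrophil genes (3 of 17 alone, 1.49, adjusted p = 3.27e-09, and 0.498) and megakaryocyte genes (5 of 12 alone, 0.65, adjusted p = 2.08e-05, and 0.502). Lower as sets were T cell markers at -0.23 (0 called, 2 alone, adjusted p = 5.00e-04, and 0.546 with an estimated correlation), NK cell markers at -0.44 (1 called higher, 4 lower alone, adjusted p = 0.00233, and 0.546) and adipose genes at -0.97 (adjusted p = 2.64e-05, and 0.546). The levels of these 3 lists overlapped between the libraries of the groups, for example 5.712 and 5.672 against 6.11 and 5.69 for T cell markers, so their directions are uncertain. Th1 genes did not pass (0.04, adjusted p = 0.603).

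**Figure D3:**
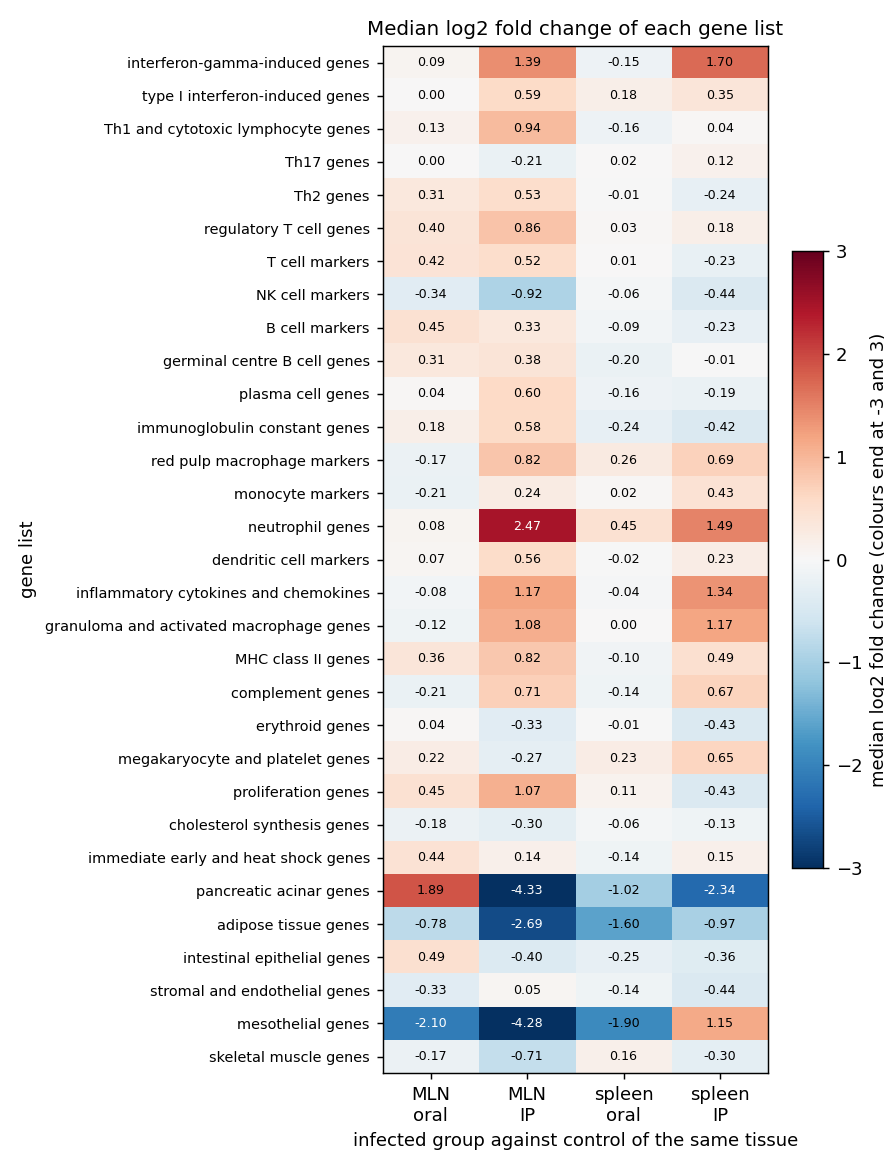
Median log2 fold change of the 31 lists (vertical) in MLN oral, MLN IP, spleen oral and spleen IP against control (horizontal); colours end at -3 and 3. Mesothelial and adipose genes are far lower in MLN IP, where scaling on T and B markers turns the monocyte median negative.

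Spleen IP and spleen oral differed by the same kind of genes. Gbp2b was 6.57 higher in IP (SE 0.452, adjusted p = 5.32e-04), Apol11a 5.74 (SE 0.532, adjusted p = 0.00239) and Acod1 5.08 (SE 0.837, adjusted p = 0.0262). Tnf was 1.60 higher (SE 0.2, adjusted p = 0.00524), Ifng 2.94 (SE 0.536, adjusted p = 0.0303), Gbp2 2.73 (SE 0.41, adjusted p = 0.0210), Cxcl9 3.07 (SE 0.545, adjusted p = 0.0459) and Il1b 2.05 (SE 0.389, adjusted p = 0.0475). Cd209b was 3.23 lower (SE 0.342, adjusted p = 0.00289), Siglech 2.05 lower (SE 0.268, adjusted p = 0.0064) and the angiotensin receptor Agtr1a 1.31 lower (SE 0.218, adjusted p = 0.0210), though not called under marker scaling. The mesothelial mucin Muc16 was 5.01 higher in IP (SE 0.773, adjusted p = 0.0210), at 15.8 CPM (SD 14.8) against 0.478.

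The count was 138 higher and 12 lower, with 1756 at an unadjusted p under 0.05. It was 8 without spleen oral 4, 17 without spleen oral 1, 32 without spleen IP 2, 95 without MLN control 1 and 93 without MLN control 3. Gbp2b, Apol11a and Cd209b were called in all 12 fits. Tnf and Muc16 lost their calls without spleen oral 1 or 4, Siglech and Gbp2 also without spleen IP 2, and Agtr1a also without spleen IP 2 or 5. Ifng lost its call without MLN control 1, MLN control 3, spleen oral 1, spleen oral 4, spleen IP 2 or spleen IP 5, and Acod1, Il1b and Cxcl9 lost theirs without those or MLN oral 4 or 5. Interferon-gamma-induced genes were higher in 26 of 31 (30 alone, median 1.81, camera adjusted p = 6.99e-110, and adjusted p = 0.0363 with an estimated correlation), though in 2 without spleen oral 4, 5 without spleen oral 1 and 10 without spleen IP 2. Inflammatory genes had 3 of 22 higher (15 higher and 1 lower alone, 1.76, adjusted p = 9.95e-17, and adjusted p = 0.0894 with an estimated correlation). Mesothelial genes had 1 of 8 higher (7 alone, 3.17, adjusted p = 2.63e-11, and 0.243) and T cell markers 1 of 16 lower (3 alone, -0.13, adjusted p = 2.61e-04, and 0.634).

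No gene was called in spleen oral against control. Dbp stood at 15.1 and 34.2 CPM (1.18, SE 0.156, adjusted p = 0.166) and the clock-controlled factor Hlf at 2.05 and 6.88 CPM (1.75, SE 0.353, adjusted p = 1). Muc16 (-3.27, SE 0.764) and the adipocyte serine protease Cfd (-3.53, SE 0.884, 15.7 and 1.35 CPM) were the largest of the lower genes picked by p that had counts in both groups, each at adjusted p = 1. Ccl19-ps1 had 0 counts in spleen oral, at least 17.8-fold lower and not called (adjusted p = 0.166). Ifng (-0.71, SE 0.555), Cxcl9 (-1.09, SE 0.515), Il1b (-0.84, SE 0.381) and Slc40a1 (0.52, SE 0.258) all had an adjusted p of 1.

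edgeR's quasi-likelihood test called 0 genes in spleen oral and 213 had an unadjusted p under 0.05; DESeq2 called 8, limma on RPKM 3, edgeR without the filter 3 and limma with the replicate block 2. Each fit that left out 1 library gave 0. As sets, adipose genes at -1.60 (0 called, 2 of 14 lower alone, camera adjusted p = 1.43e-21, and adjusted p = 0.162 with an estimated correlation) and mesothelial genes at -1.90 (0 called, 3 of 8 alone, adjusted p = 6.07e-22, and 0.162) were lower. Interferon-gamma-induced genes at -0.15 and Th1 genes at -0.16 (0 called, adjusted p = 0.00109 each, and 0.712 with an estimated correlation) passed as lower, and red pulp markers at 0.26 (0 called, 0 alone, adjusted p = 0.0020, and 0.712) as higher. The libraries overlapped in all 3 lists, with the interferon-gamma list at 6.01 and 5.85 in spleen oral, between spleen control 2 at 6.37 and spleen control 3 at 5.61, so these directions are uncertain.

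The change with IP differed between tissues for many genes. IP libraries were numbered 3 and 4 in MLN and 2 and 5 in spleen, so a difference between animals cannot be told apart from one between tissues. Gbp2b rose by 5.76 in spleen but stood at 0.67 in MLN, where control was already at 78.4 CPM (difference spleen minus MLN 5.09, SE 0.523, adjusted p = 0.0108). The lymphoid chemokine Ccl19 (ENSMUSG00000071005, chr4:42754525-42756577) stood at 1.61 in MLN and -0.44 in spleen (difference -2.05, SE 0.236, adjusted p = 0.0108). Whether its reads are shared with copies was not examined. Igha stood at 2.84 in MLN and 0.05 in spleen (difference -2.79, SE 0.418, adjusted p = 0.0118), and Cd4 at 1.16 and -0.28 (difference -1.44, SE 0.247, adjusted p = 0.0170), the latter not called under marker scaling (adjusted p = 0.113), which Cd4 helps define. Wt1 stood at -3.92 in MLN and 0.03 in spleen (difference 3.95, SE 0.631, adjusted p = 0.0151).

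The interaction test of edgeR called 658 genes with a higher and 409 with a lower change in spleen than in MLN, and 4216 had an unadjusted p under 0.05. Marker scaling gave 2305 and 26, with the median of all genes at 0.671, and relative log expression scaling 585 and 579. The total was 307 without MLN control 1, 412 without MLN control 3, 382 without MLN IP 3, 127 without MLN IP 4, 530 without spleen control 3, 500 without spleen oral 1, 507 without spleen oral 4 and 48 without spleen IP 2. Gbp2b and Ccl19 were called in all 12 fits, Igha and Cd4 in all but the fit without spleen IP 2, and Wt1 in all but those without MLN IP 4 or spleen IP 2. Mesothelial genes were higher in 8 of 8 (8 alone, median 5.36, camera adjusted p = 4.55e-11, and adjusted p = 0.469 with an estimated correlation), while Th1 genes were lower in 6 of 20 (10 alone, -0.93, adjusted p = 2.63e-07, and 0.469), T cell markers in 6 of 16 (9 alone, -0.74, adjusted p = 9.60e-08, and 0.636) and immunoglobulin constant genes in 3 of 12 (5 alone, -1.90, adjusted p = 1.08e-05, and 0.469). Interferon-gamma-induced genes had 1 of 31 higher (1 alone, 0.23, adjusted p = 0.0279, and 0.872).

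**Figure D4:**
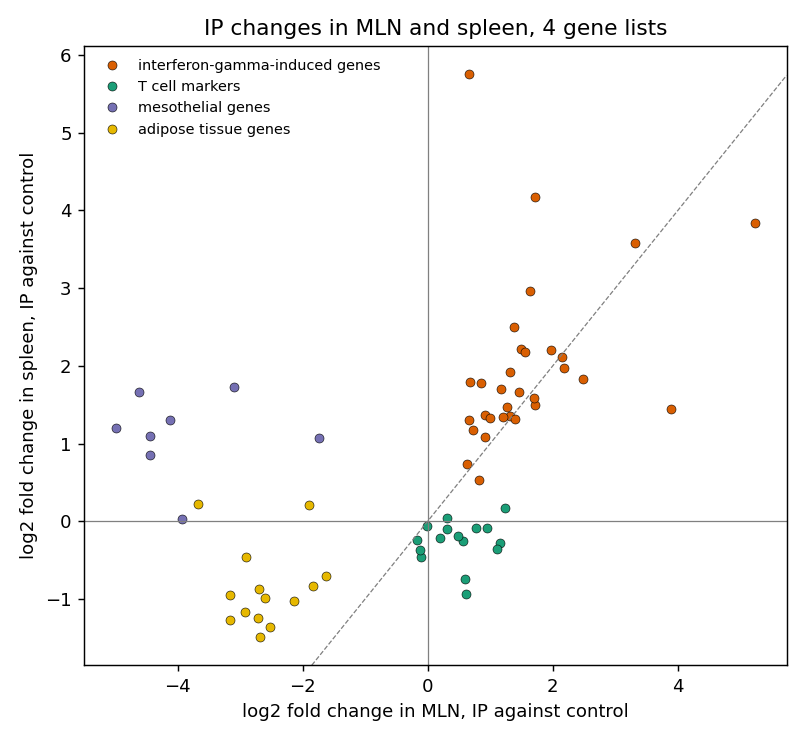
Log2 fold change of IP against control in MLN (horizontal) and spleen (vertical); each point is a gene of the interferon-gamma, T cell, mesothelial or adipose list, and the dashed line marks equal change. Most interferon-gamma genes lie on the positive side in both tissues, and mesothelial genes lie on the negative side in MLN.

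For the oral route, 0 genes differed between tissues in their change. Flacc1 had a difference of 2.55 (SE 0.535), the platelet factor Pf4 1.97 and Il2rg, the common cytokine receptor chain, -0.81, each at adjusted p = 0.999. By edgeR 696 genes had an unadjusted p under 0.05, and DESeq2 called 1. The count was 92 (20 higher, 72 lower) without MLN oral 5 and 1 without MLN control 1 or MLN control 3. As sets, B cell markers at -0.52 (0 called, 0 alone, camera adjusted p = 4.63e-06, and adjusted p = 0.471 with an estimated correlation) and T cell markers at -0.39 (0 called, 0 alone, adjusted p = 8.25e-06, and 0.471) had a lower change in spleen than in MLN under TMM scaling. Marker scaling, which these markers define, puts the median of all genes at 0.42, so the direction depends on the choice of reference. The interferon-gamma list stood at -0.21 (0 called, 0 alone, adjusted p = 0.0241, and 0.875).

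**Figure D5:**
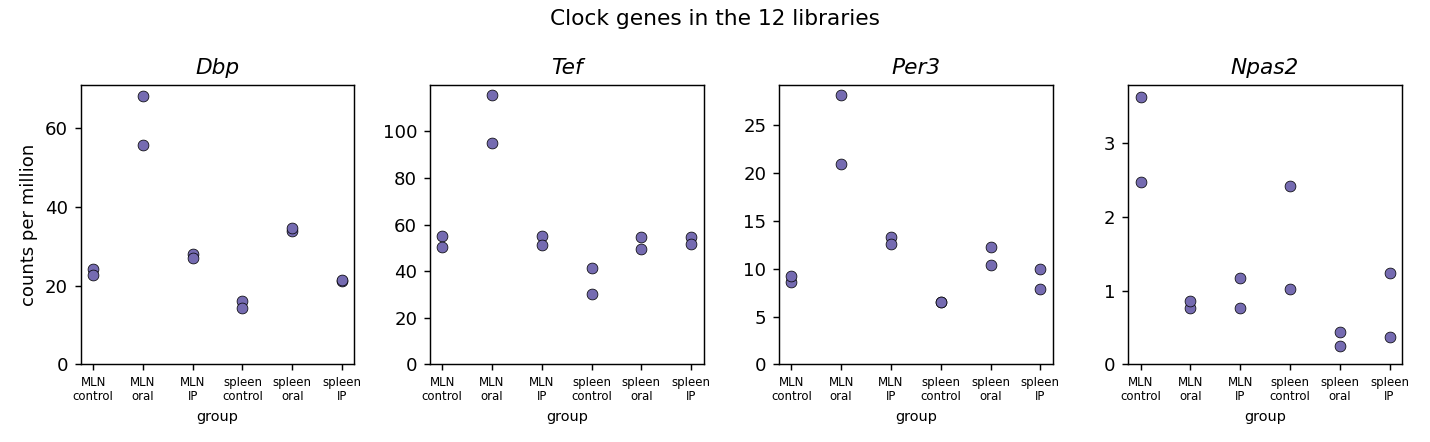
CPM of the clock genes Dbp, Tef, Per3 and Npas2 in the 12 libraries, by group; each point is 1 library. Dbp is highest in the oral group of both tissues, with a call in MLN that scaling on T and B markers removes.

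Oral and IP changes were also set against each other over all genes within a tissue. In MLN the Pearson correlation of the oral and IP fold changes was 0.376, and 0.501 (0.482 to 0.541) in 20 simulations that shared controls but no effect. In spleen it was 0.384, and 0.505 (0.463 to 0.537) in the simulations. The simulated IP groups held no changed genes. Real IP changes widen the IP values and can lower the correlation by themselves, so a value below the simulated one does not show less alike changes. The rank correlation was higher in MLN, 0.57, and lower in spleen, 0.312, without a simulated level for it. The covariance in MLN was 0.281, above the simulated mean of 0.147, and that in spleen 0.144, near the simulated 0.156. The excess was thus 0.133 in MLN and -0.0126 in spleen. Both changes use the same 2 control libraries, and an oral and an IP change from separate controls was not run.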

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

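The tests of the 3 explanations weighed at the end of this part were chosen only after the result was seen, while the interaction and list tests were planned. The IP change differed between spleen and MLN in 1067 genes by edgeR's interaction test with Benjamini-Hochberg adjustment, and values here are the change in spleen minus the change in MLN. Scaled on T and B cell markers, 2305 genes had a higher and 26 a lower change in spleen.

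Mesothelial genes stood apart. Upk1b differed by 6.28 (SE 1.117, adjusted p = 0.0216), Bnc1 by 6.21 (adjusted p = 0.0350), Upk3b by 6.19 (SE 1.044, adjusted p = 0.0217), Muc16 by 4.82 (SE 0.953, adjusted p = 0.0248) and Wt1 by 3.95 (SE 0.631, adjusted p = 0.0151). Upk3b was -4.98 in MLN and 1.20 in spleen, where the IP libraries spread widely (37.1 CPM, SD 29). The desaturase Scd1 differed by 2.45 (SE 0.463, adjusted p = 0.0211), the vitamin E carrier Ttpa by 5.80 (adjusted p = 0.0324), the neutrophil gene Wfdc21 by 2.63 (adjusted p = 0.0346), Apol6 by 5.95 (adjusted p = 0.0298) and Gbp2b by 5.09 (SE 0.523, adjusted p = 0.0108). Each of these calls held under marker scaling, which moves the differences of all genes upward (median from 0.065 to 0.671). That scaling favours positive differences such as these and is a weak check of them. All except Gbp2b were lost without spleen IP 2, where the total was 48, and Wt1 was lost without MLN IP 4 as well. The others of them were called in 5 to 9 of 12 fits. In spleen Ttpa stood at 0.0301 CPM in control and 0.149 CPM in IP, and Apol6 at 0.181 CPM in control. These levels lie around the floor of 0.0903 CPM in spleen control, so the size of both differences is uncertain.

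Some lymphocyte and antibody genes had a more positive IP change in MLN than in spleen. The T cell factors Tcf7, Bcl11b and Lef1 differed by -1.35 (SE 0.21, adjusted p = 0.0129), -1.46 (adjusted p = 0.0151) and -1.56 (adjusted p = 0.0183), and Cd4 by -1.44 (SE 0.247, adjusted p = 0.0170). Th1 genes followed, with Tbx21 at -1.81 (SE 0.36, adjusted p = 0.0225), Eomes at -1.83 (adjusted p = 0.0250), Cxcr3 at -1.25 (adjusted p = 0.0257), and Stat4 at -1.16 (adjusted p = 0.0312). The regulatory cytokine Tgfb1 differed by -0.94 (adjusted p = 0.0322). The B lineage factors Spib and Irf4 differed by -0.98 (adjusted p = 0.0444) and -1.05 (adjusted p = 0.0324). Igha differed by -2.79 (SE 0.418, adjusted p = 0.0118), Igkc by -2.38 (adjusted p = 0.0340) and Ighg1 by -4.81 (adjusted p = 0.0317). Of these, Lef1, Igha and Ighg1 held under marker scaling, and Tcf7, Bcl11b, Cd4, Tbx21, Eomes, Cxcr3, Stat4, Tgfb1, Spib, Irf4 and Igkc did not. T and B cell markers among them help define that scaling. Every one was lost without spleen IP 2, and of these Igha, Tcf7, Bcl11b and Cd4 were called in the other 11 fits.

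The stromal and endothelial list had 3 of 19 lower (3 adjusted over the list alone, median -0.15, camera adjusted p = 0.0454, and adjusted p = 0.872 with an estimated correlation). Its chemokine Ccl19 differed by -2.05 (SE 0.236, adjusted p = 0.0108) and Ccl21a (ENSMUSG00000094686, chr4:42772860-42773993), whose reads are shared between copies, by -1.87 (SE 0.253, adjusted p = 0.0108). Whether reads of Ccl19 are shared with copies was not examined, and fits that leave out a library cannot show it. The vessel addressin Madcam1 differed by -1.50 (adjusted p = 0.0296). From outside that list, the matrix protease Mmp3 differed by -3.06 (adjusted p = 0.0289) and the substance P receptor Tacr1 by -2.88 (adjusted p = 0.0333). Ccl19 and Ccl21a were called in all 12 fits, whereas Madcam1, Mmp3 and Tacr1 were lost without spleen IP 2. Madcam1 and Tacr1 also lost the call under marker scaling. Ccl19-ps1 had a fitted difference of -9.18 (adjusted p = 0.0108), a value set by 0 counts in spleen IP.

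A rise of lymphoid and myeloid genes in MLN IP could follow from less pancreas and fat in the MLN IP samples, which would raise every lymph node gene alike. Against this, the interferon-gamma list rose by a median of 1.39, which is 1.04 more than the 0.35 of the T and B cell markers. The SE of that difference, from a bootstrap over genes and not over libraries, was 0.161. After marker scaling 16 of the 31 genes were still called. These values argue against a uniform shift as the whole rise of the interferon-gamma list, although the SE does not measure the spread between the 2 libraries of a group. The smaller rise of T and B cell markers may still be such a shift.

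The fall of fat, mesothelial and pancreatic genes in MLN IP could reflect less attached fat, mesothelium and pancreas in the dissected MLN IP samples. Structural adipocyte genes such as Plin1 and Adipoq had a median of -2.51 and nutrition-driven ones such as Lep and Lpl -2.81, a difference of 0.3. The adipose share was at most 0.717% in MLN IP and at least 1.28% in the other MLN libraries, and the group is the same split as the dissection. Loss of fat in the animal and less attached fat at dissection cannot be told apart here.

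Ccl19-ps1, with 0 counts in 3 of the 6 groups, could reflect reads shared between near-identical gene copies. In 12 of 12 libraries reads fell on exactly 1 of Ccl19-ps1 and Gm50471, for example 88 and 0 in each MLN IP library. Both libraries of every group fell on the same copy. A real difference between the animals in which copy is transcribed would give the same split, so the split does not favour shared reads. The sum of the copies was -0.589 (SE 0.376, adjusted p = 0.606) in MLN oral, 0.393 (SE 0.346, adjusted p = 1) in spleen oral and -0.286 (SE 0.356, adjusted p = 0.825) in spleen IP, none called. For MLN IP the sum was not fitted. There Gm50471 had 0 counts in the control and IP libraries, and edgeR called Ccl19-ps1 higher (1.55, adjusted p = 0.0240), which the exchange of copies does not cover. Which copy was transcribed stays open.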

How the results depend on the processing

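The test and the unit moved most counts of called genes. DESeq2 called 138 genes in MLN oral against control where edgeR called 1, 2117 in MLN IP against oral, 8 in spleen oral, 349 in spleen IP against control, 358 in spleen IP against oral, 1 for the oral tissue difference and 2201 for the IP tissue difference. limma on RPKM called 21 in MLN oral, 2360 in MLN IP (1340 higher, 1020 lower), 714 in MLN IP against oral (522 higher, 192 lower), 3 in spleen oral, 47 in spleen IP, 69 in spleen IP against oral and 185 for the IP tissue difference (154 higher, 31 lower), with the median of all genes at 0.149 in MLN IP, 0.285 in MLN IP against oral, -0.134 in MLN oral and 0.176 for the oral tissue difference. The limma fit on RPKM used no TMM scaling, so test, unit and scaling changed together there. Which of them caused the difference was not tested.

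Without the filter 11 genes were called in MLN oral and 3 in spleen oral. The fit to the 6 libraries of a tissue called 0 in MLN oral, 509 in MLN IP against oral, 43 in spleen IP and 55 in spleen IP against oral. Without trend and robust spread 0 were called in MLN oral, 593 in MLN IP against oral and 561 for the IP tissue difference (410 higher, 151 lower). Marker scaling, chosen after seeing the data, called 297 in MLN IP against oral and 2331 for the IP tissue difference. It put the median of all genes at 0.202 in spleen IP, 0.201 in spleen IP against oral and 0.42 for the oral tissue difference. Spleen against MLN was at 7318 to 9318 in every setting.

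A replicate block joined samples of the same group and number in both tissues as a random effect in limma, and called 2 genes in spleen oral (1 higher, 1 lower). The same voom fit without the block also called 2. The block correlation was -0.0056, and the samples share a number, not a stated animal. It rests on control 3 and oral 4, the only numbers found in both tissues. No IP library was joined to another, so the block hardly tests the IP results.

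With each library left out in turn, the counts ran from 0 to 247 in MLN oral, 1545 to 4580 in MLN IP, 30 to 2235 in MLN IP against oral, 12 to 129 in spleen IP, 8 to 178 in spleen IP against oral, 0 to 92 for the oral and 48 to 1445 for the IP tissue difference. The library left alone in its group was assumed to vary like the other groups.

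Of 15369 results of a named gene under a setting, genes not called included, 14014 had the same call status, 278 gained a call and 1077 lost one. Among genes called in the planned edgeR fit or under the setting, 0 changed direction. A change of sign in a gene called in neither counted as the same, so the direction of such genes is not covered. Calls made with all 12 libraries were less stable. With each library left out, 0 of 1 named call was held throughout in MLN oral, 43 of 95 in MLN IP, 1 of 58 in MLN IP against oral, 6 of 24 in spleen IP, 3 of 28 in spleen IP against oral, 4 of 30 for the IP tissue difference and 81 of 84 in spleen against MLN. The fit to the 6 libraries of a tissue called 83 of the 95 in MLN IP and 10 of the 24 in spleen IP. Of the 95 named genes called in MLN IP, DESeq2 called 86, relative log expression scaling 94, RPKM 82 and marker scaling 65. Of the 24 called in spleen IP, the numbers were 24, 20, 12 and 23. Depth limits genes such as Il17a, with 7 to 16 counts in an MLN library.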

Other observations

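The gene families and the tests of the clock pattern in this part were chosen only after the result was seen, while the comparisons and the exchange of tissue labels were planned. Among 15 MHC class I heavy chain genes, a family picked after values were seen and tested gene by gene with edgeR and Benjamini-Hochberg adjustment, 7 were higher in spleen IP (median 1.04) and 9 higher and 1 lower in MLN IP (median 0.67), though near-identical copies make single members uncertain. Their activator Nlrc5 rose by 1.41 in spleen (adjusted p = 0.0120) and 1.09 in MLN (adjusted p = 0.0048). The interleukin-18 antagonist Il18bp was at 1.53 in spleen and 1.44 in MLN, and Batf2 rose by 2.33 (adjusted p = 0.0310) and 2.52 (adjusted p = 0.0033). The nuclear receptor Nr1h3, which controls macrophage lipid handling, rose in spleen by 1.27 (SE 0.149, adjusted p = 0.0052) and stood at 0.02 in MLN.

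Guanylate-binding protein genes were higher in 11 of 11 in spleen IP (median 2.18) and 10 of 11 in MLN IP (median 1.496). Of 13 apolipoprotein L genes 3 were higher in spleen IP (median 2.12) and 3 in MLN IP (median 0.17). Of 6 Cd209 lectin genes, 1 was lower in spleen IP (median -2.42), 5 in MLN IP (median -1.84) and 3 in spleen IP against oral (median -2.52). Ly49 receptor genes (Klra), made by NK cells, had medians of -1.20 in spleen IP and -1.17 in MLN IP, with 1 of 10 higher in spleen and 1 higher and 3 lower in MLN. These families too were picked after values were seen, their members share reads, and no test of a family as a set was run.

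Of 9 output genes of the circadian clock, put together after Dbp, Per3 and Tef had been seen, 8 had a positive change in MLN oral (median 1.37) and 9 in spleen oral (median 0.685). Collection of the oral samples at another time of day could give this pattern. The 5 genes of the opposite phase had a median of -0.25 over both tissues, with 3 of 5 negative in MLN and 5 of 5 in spleen. The standard error of their mean was 0.272, taken over genes and tissues and not over libraries. Set tests by fry were run on both groups of clock genes, but as the pattern had chosen the genes their p-values are not used. The oral libraries numbered 4, whether of the same animal or not, did not alone carry the change of Dbp. Without them, with 1 library left in each oral group, Dbp was still at 1.54 in MLN and 1.16 in spleen. The other output genes were not examined this way, so the pattern as a whole is not covered. Infection and time of collection cannot be told apart, because the labels give no time.

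The difference between spleen and MLN gave more genes than any exchange of tissue labels that was drawn. When tissue labels were exchanged within each route, 1 of 100 splits, the real one, gave as many as its 9221 genes. The highest other gave 6318 and the median of the others was 0. Splits that put both tissues into a group widen the spread within it, and 1 of 100 is the least this count can give. No conclusion on chance is therefore drawn from it.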
